A study of Mus musculus with 6 samples.

How the data were processed

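The series holds RNA sequencing of mouse intestine from 6 samples, 3 labelled control and 3 labelled NEC, the abbreviation of necrotizing enterocolitis. Per the labels' protocols, control mice were dam-fed. NEC mice received 40 µl of 33% Esbilac formula by gavage every 4 h for 96 h, and every 12 h they spent 100 s in 99.9% nitrogen and then 10 min at 4 °C. Total RNA was extracted with TRIzol and sequenced as 150 bp read pairs on an Illumina NovaSeq, per the labels' protocols. The segment of intestine, the age and sex of the mice and the strand setting are not given in the sources used here. The labels do not state that each sample came from a separate animal, so p-values measure the spread between these samples, which may in part be technical. Control replicate 1 held both Xist and Y-linked counts, so that library may hold RNA of more than 1 mouse.

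The authors deposited 1 table of whole-number gene counts for the 6 samples, and the genome build named in the submitters' processing notes is mm10. The aligner, the counter and the gene annotation are not given in the sources used here. The table lists 54446 gene identifiers, of which 54409 matched a gene symbol and 37 did not, and 29684 had a count above 0 in at least 1 sample. Total counts were 77953991, 69441184 and 106304239 in control replicates 1 to 3 and 97445491, 75673833 and 74912430 in NEC replicates 1 to 3. Low counts gathered at multiples of 4, which were 1.96 times as frequent as neighbouring values, so 1 sequenced fragment may stand for about 4 counts and the totals may overstate the number of fragments. The quasi-likelihood test estimates the spread from the replicates and so does not take the counts as independent fragments. All 37 mitochondrial genes were at 0 in every library, while the mitochondria-like pseudogenes Gm28661, Gm28437, Gm29216 and Gm10925 together took 1.77% to 3.95% of the counts. Since the strand setting is not stated, counts of overlapping genes on opposite strands cannot be told apart, and close paralogs may share counts.

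Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes kept by filterByExpr, with its minimum count of 10, numbered 19176. Library sizes were scaled by TMM, dispersions were estimated with robust=TRUE, and NEC was compared with control by the quasi-likelihood F test with Benjamini-Hochberg adjustment. A gene was called changed at an adjusted p below 0.05. A positive log2 fold change means higher in NEC, SE is the standard error of the log2 fold change, and intervals are 95% intervals from the same fit. CPM values, counts scaled to a common library size after TMM, are given as mean ± SD over the 3 libraries of a group. For Hdac8 a two-sided exact permutation test of log2 CPM was added, whose smallest possible p is 0.1 with 3 samples against 3. Positions are those of GENCODE release M21 on mm10, counted from 1.

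Before the data were examined, 42 gene lists, the tests, the alternatives and the rule for named genes were fixed. The lists were tested with limma 3.58.1 on log2 CPM with a prior count of 2, using camera with a preset correlation of 0.01, camera with an estimated correlation, and fry, with adjustment over the 42 lists. They cover histone deacetylases, sirtuins, 4 lists of arginine, proline and polyamine genes, transport, inflammation, interferon response, stress, metabolism, clock, regional and epithelial genes, and markers of other cell types. For each list, counts of called members are given over all genes tested and adjusted over the list alone. The named genes were all histone deacetylases, the 10 largest rises and the 10 largest falls among called genes with groups that did not overlap and a mean CPM of at least 5 (leaving out unnamed gene models, pseudogenes and immune receptor segments), up to 4 members per list with the smallest raw p (up to 8 for the 4 arginine, proline and polyamine lists), the 5 most abundant genes, and 5 sex-linked genes given as values only.

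The procedure was tested on simulated counts for the 19176 genes with 200 changed genes, 50 at each size. It recovered 2.0%, 36.0%, 60.0% and 80.0% of the genes changed by a log2 fold change of 1, 2, 3 and 4, and 4 of its 93 calls were unchanged genes. A simulated shift of 1 list was found by camera, and 0 of the 41 other lists were called. The simulated genes varied independently, so this does not measure camera's errors where members of a list vary together. In the data the estimated correlation ran from -0.037 to 0.75 over the lists, with 0.258 for interferon response genes. Comparison of the libraries found none that differed by as little as sampling noise.

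The alternatives were RLE, upper quartile and library-size scaling, no low-count filter, a filter of at least 50 counts in at least 3 samples, DESeq2 1.42.0, limma-voom, robust=FALSE, the replicate number as a block, the first 8 characters of the sample code in the labels (AG181017 or AG181028) as a term, the 4 AG181017 samples alone, each library left out in turn, removal of the 20 most abundant genes, and a threshold of 0.01. Counts divided by 4, a covariate from Y-linked genes, a fit without the 2 controls that carried Xist counts, and 6 further gene lists were added after seeing the data.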

Results

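Intestinal RNA of 3 samples from dam-fed control mice was compared at 96 h with that of 3 samples from mice put through formula feeding, hypoxia and cold stress (NEC). Total counts per library ranged from 69441184 to 106304239. The first 2 principal components of log2 CPM held 36.4% and 28.2% of the variance. The 5 most abundant genes were the apolipoproteins Apoa4 and Apoa1, the lysosomal protease Lgmn, and the mitochondria-like pseudogenes Gm28661 and Gm28437. None of these 5 passed the edgeR test, and Apoa4 alone took between 3.37% and 10.4% of the counts of a library.

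The series title names the class I histone deacetylase HDAC8, which it describes as elevated, and arginine-proline metabolism, so Hdac8 mRNA was examined first. The title does not state whether RNA or protein was measured. Hdac8 (ENSMUSG00000067567, chromosome X, 102284639 to 102505359, minus strand) had 9.69 ± 1.40 CPM in control and 7.17 ± 1.46 CPM in NEC (SD, n = 3 each). Every NEC library lay below every control library, with a log2 fold change of -0.44 (SE 0.29, 95% interval -1.10 to 0.23) and an edgeR adjusted p of 0.527. The gap was narrow, from 8.71 CPM in NEC replicate 2 to 8.87 CPM in control replicate 1. Groups did not overlap in 22.4% of all genes tested. The two-sided exact permutation p was 0.1, the smallest that 3 samples against 3 allow. None of the 11 histone deacetylases measured passed the test, over all genes or adjusted over the list alone. The class IIa member Hdac5 had the smallest p of them, at 79.6 ± 13.4 CPM in control and 47.3 ± 11.7 CPM in NEC (log2 fold change -0.75, SE 0.26, edgeR adjusted p = 0.233). Log2 fold changes of the others, of which Hdac4, Hdac7 and Hdac11 overlap genes on the opposite strand, were -0.23 for Hdac1, 0.23 for Hdac2, -0.24 for Hdac3, -0.11 for Hdac4, -0.55 for Hdac6, 0.05 for Hdac7, -1.52 for Hdac9, -0.19 for Hdac10 and -0.12 for Hdac11. Leaving out 1 library moved Hdac9 between -2.86 and -1.07. The histone deacetylase list had a median of -0.23 (-0.46 to -0.21 with 1 library left out) and a camera adjusted p of 0.123. Of the 7 sirtuins, none passed over all genes and Sirt3 (log2 fold change -1.01, SE 0.26) was the 1 member lower when adjusted over the list alone, with a camera adjusted p of 0.404 for the list.

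**Figure D1:**
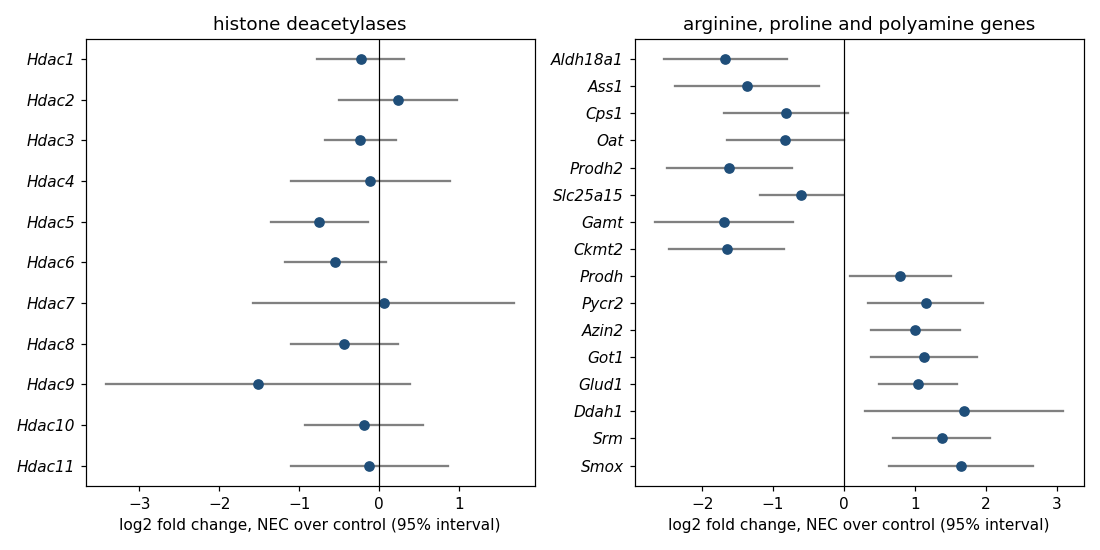
Log2 fold changes (NEC over control, points) with 95% intervals (lines) for the 11 histone deacetylases on the left and 16 genes of arginine, proline and polyamine metabolism on the right. The genes on the right were picked from the members with the smallest raw p in their lists, and the intervals are not adjusted for that choice. No gene in either panel passed the edgeR test over all genes. The interval of Hdac8 runs from -1.10 to 0.23, and that of Aldh18a1 from -2.54 to -0.81.

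Among genes of arginine and proline metabolism, none of those measured passed the test over all genes, and the members with the smallest p went in both directions. Aldh18a1, which makes the pyrroline-5-carboxylate precursor of proline and ornithine, had 557 ± 217 CPM in control and 174 ± 50.5 CPM in NEC (log2 fold change -1.68, SE 0.37, edgeR adjusted p = 0.0962). Ass1, which makes argininosuccinate, had a log2 fold change of -1.37 (SE 0.44), Oat of -0.83 (SE 0.36) and the urea cycle enzyme Cps1 of -0.82 (SE 0.38). Glud1 (1.04, SE 0.24), Got1 (1.13, SE 0.32) and the proline oxidase gene Prodh (0.79, SE 0.31) had positive values. In arginine and citrulline synthesis 0 of 14 members passed over all genes, and 2 were higher and 1 lower adjusted over the list alone, with a median of -0.33 and a camera adjusted p of 0.461. That median ran from -0.53 to -0.23 when 1 library was left out. In proline metabolism 0 of 14 passed over all genes and 2 were lower adjusted over the list alone, Aldh18a1 and Prodh2 (-1.62, SE 0.38), with a camera adjusted p of 0.522. In arginine breakdown, nitric oxide and creatine genes 0 of 15 passed over all genes. Adjusted over the list alone the creatine genes Ckmt2 (-1.66, SE 0.35) and Gamt (-1.69, SE 0.42) were lower and Azin2 (1.01, SE 0.27) was higher, with a camera adjusted p of 0.784. Of 10 polyamine genes 0 passed over all genes, and the spermidine synthase gene Srm (1.38, SE 0.30) and the spermine oxidase gene Smox (1.65, SE 0.44) were higher adjusted over the list alone, with a camera adjusted p of 0.522. Over the 61 measured members of the histone deacetylase, arginine, proline and polyamine lists together, edgeR called 0, 16 had an unadjusted p below 0.05, and 8 passed adjusted over these alone. Over all 19176 genes tested 2992 had an unadjusted p below 0.05. DESeq2 called 11 of the 61 members and limma-voom called 0. The simulation recovered 2.0% and 36.0% of genes changed by a log2 fold change of 1 and 2, so 0 calls do not show an absence of change.

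Across the transcriptome, 135 of 19176 genes tested were changed, 50 higher and 85 lower in NEC, all by at least 2-fold. Among called genes with a mean CPM of at least 5, leaving out unnamed gene models, the largest falls were in Nr0b2, a bile acid-responsive nuclear receptor, at 19.2 ± 6.16 CPM in control and 0.192 ± 0.109 CPM in NEC (log2 fold change -6.66, SE 0.55, edgeR adjusted p = 0.015), and in genes known for interferon induction, with 10.2 CPM against 0.136 CPM for Ifi44, 141 against 2.77 for Ifit3 and 100 against 2.29 for Isg15. The interferon-inducible genes Zbp1, Ifit3b, Herc6 and Trim30a fell, with log2 fold changes between -5.39 and -3.77, and Cttnbp2 (-3.90, SE 0.59) and the nuclease gene Dnase1 (-3.79, SE 0.40) fell too. With the same limits the largest rise was in Zbtb16, a glucocorticoid-induced transcription factor gene, from 0.295 ± 0.0814 to 10.1 ± 6.56 CPM (log2 fold change 5.08, SE 0.70, edgeR adjusted p = 0.0378). Mmp7, a matrix protease made by Paneth cells in adult intestine, rose from 1.43 ± 0.552 to 30.8 ± 24.6 CPM. Gsta1 (log2 fold change 4.21, SE 0.69), Epop (4.18, SE 0.64), the urokinase receptor gene Plaur (3.95, SE 0.55), Efhd1 (3.93, SE 0.60), Slc22a4 (3.29, SE 0.52) and the EGF receptor ligand gene Ereg (3.24, SE 0.51) rose as well. Gsta1 has close paralogs that may share its counts. The counts of Efhd1, Ereg, Mmp7, Cttnbp2 and Dnase1 may include those of genes on the opposite strand.

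**Figure D2:**
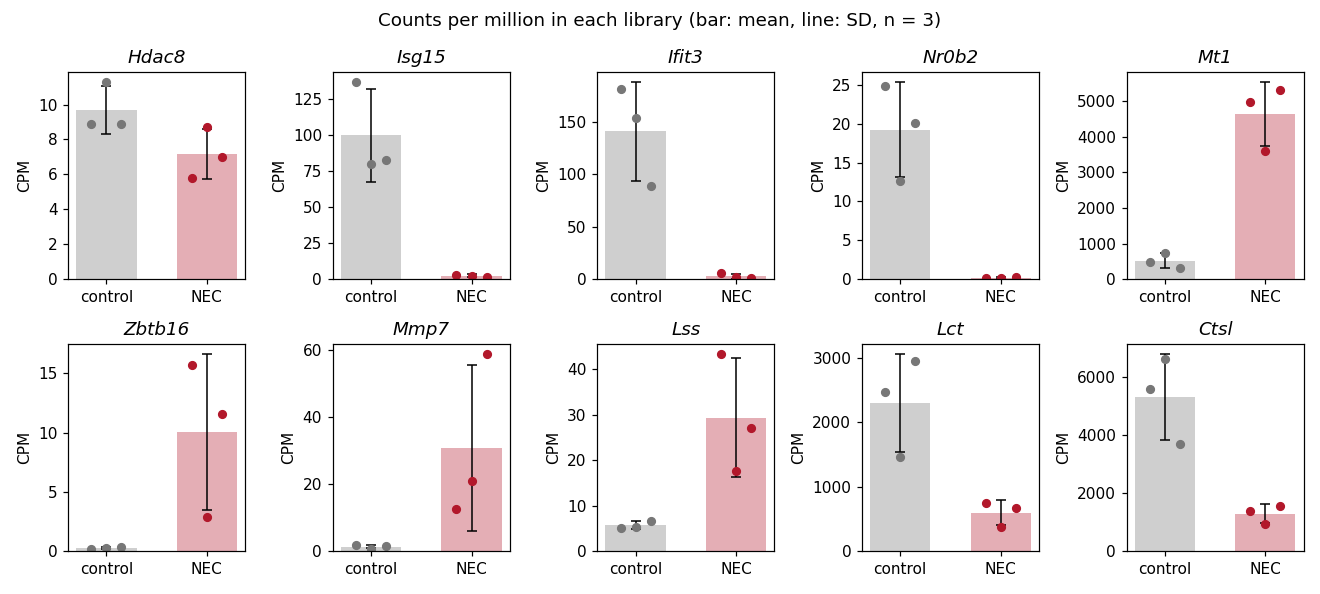
CPM of 10 genes in each of the 6 libraries (points), with the group mean (bar, starting at 0) and SD (line), n = 3 per group. Isg15 averaged 100 CPM in control and 2.29 CPM in NEC, and Mt1 averaged 513 CPM in control and 4630 CPM in NEC.

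In all 135 genes the groups did not overlap, which held for 22.4% of the genes tested against 10% given by chance, and 2992 genes had an unadjusted p below 0.05. The count of 135 depended on single libraries. It was 0 without control replicate 1, 3 without NEC replicate 3, 25 without control replicate 3, 34 without NEC replicate 1, 106 without control replicate 2 and 101 without NEC replicate 2, and all 135 kept their sign in each of these fits. Within the 4 AG181017 samples 25 genes were called, the AG181028 code has 1 sample per group and gives no test, and all 135 had the same sign within both. Groups that do not overlap all but fix these signs in advance, so the kept signs are no separate support. As a measured fact on the animals, Xist stood at 179 and 344 CPM in control replicates 1 and 2 and at 1.17 CPM or below in the other 4 libraries. The Y-linked genes were near 0 in control replicate 2 alone, with Ddx3y at 1.29 CPM, Eif2s3y at 1.38, Kdm5d at 0.26 and Uty at 0.42. In control replicate 1 both Xist and Y-linked genes were present, with Ddx3y at 19.8 CPM. None of the 135 genes lies on chromosome X or Y, which hold 653 of the genes tested. This is no test of sex as a cause, since sex-linked genes varied widely among the controls and could hardly be called. Even Xist, at 174 ± 171 CPM in control (SD, n = 3) and lower in every NEC library, is not among the 135 called genes. The count was 49 with the Y-linked signal as a covariate and 1 without control replicates 1 and 2, which leaves 1 control whose spread is assumed to be that of the NEC group.

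Of the 42 lists, 14 passed camera with the preset correlation, 8 higher and 6 lower in NEC. None passed with an estimated correlation, where the smallest adjusted p was 0.359. By fry, 2 lists passed in 1 direction, interferon response and suckling-type enterocyte genes, and 25 passed when either direction was counted. Without NEC replicate 2, 9 lists passed camera. Within the 4 AG181017 samples 13 lists passed, and the calls of the hypoxia response (adjusted p = 0.114), oxidative stress response (0.0545), PPARa targets and fatty acid oxidation (0.0791) and proximal intestine genes (0.228) ended, while inflammatory cytokines and chemokines (0.0227), macrophage and monocyte markers (0.0396) and goblet cell markers (0.0491) passed upward. Without control replicates 1 and 2, 10 lists passed, and the calls of erythroid markers (0.306), suckling-type enterocyte genes (0.0793), hypoxia response (0.194) and cell death and inflammasome (0.0535) ended.

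Interferon response genes were lower in NEC and had the smallest camera p of the 42 lists. All 20 members measured had negative log2 fold changes, with a median of -2.13, and 9 fell over all genes tested and 17 adjusted over the list alone (camera adjusted p = 9.79e-17). The adjusted p was 0.359 with an estimated correlation. Isg15 fell 43.6-fold (log2 fold change -5.45, SE 0.46), Zbp1 fell 42.1-fold (-5.39, SE 0.52), Ifi44 fell 73.2-fold (-6.19, SE 0.60) and Ifit3 fell 50.7-fold (-5.66, SE 0.74). Between 0 and 8 members fell when 1 library was left out, with 0 without control replicate 1 and without NEC replicate 3, and 4 without control replicate 3 or NEC replicate 2. The median stayed between -2.42 and -1.90 in those fits. Of the leukocyte marker lists, neutrophil markers passed camera upward (median 2.66, camera adjusted p = 0.000206), and the others did not pass. Medians of the others were 0.60 for 14 macrophage and monocyte markers (camera adjusted p = 0.382) and -0.050 for 11 T cell markers (0.720, and a median of 0.041 with library-size scaling). The median was -0.65 for 7 B cell markers (0.461), all of which had negative values. Of the macrophage markers, the haemoglobin scavenger receptor gene Cd163 rose (log2 fold change 3.71, SE 0.54), and adjusted over the list alone 2 were higher, Cd163 and Cd68, and 2 were lower, including Csf1r. The median of macrophage and monocyte markers was 0.058 without NEC replicate 2, and 0.83 without NEC replicate 1, where the list passed upward (adjusted p = 0.0291).

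Genes of the cold and glucocorticoid response, cholesterol synthesis and the oxidative stress response were higher in NEC as lists. In the cold and glucocorticoid response list 4 of 13 genes rose over all genes and 9 adjusted over the list alone, with a median of 1.88 (camera adjusted p = 2.98e-09, and adjusted p = 0.430 with an estimated correlation). The metallothionein genes Mt1 and Mt2 rose 9.02-fold and 10.5-fold (log2 fold changes 3.17, SE 0.40, and 3.39, SE 0.36), and Dusp1 rose 5.39-fold, beside Zbtb16. Dusp1 and Lss also overlap genes on the opposite strand. Gm45774, named here after its value was seen, lies on the opposite strand of Mt2 and had a log2 fold change of 3.37, and their counts cannot be told apart. All 18 cholesterol synthesis genes had positive values with a median of 1.35 (camera adjusted p = 1.03e-09, and adjusted p = 0.430 with an estimated correlation). Of them Lss, which makes lanosterol, rose over all genes (log2 fold change 2.36, SE 0.38), and 14 were higher adjusted over the list alone, including Fdps (1.77, SE 0.34). Oxidative stress genes had a median of 1.12 with 0 of 12 past the test over all genes and 3 higher adjusted over the list alone, namely Gpx2 (1.84, SE 0.36), Gsr (1.60, SE 0.36) and Nqo1 (1.55, SE 0.35). Their camera adjusted p was 0.00287, and the adjusted p was 0.436 with an estimated correlation. Without NEC replicate 1 the median of the oxidative stress response was 0.52 (adjusted p = 0.0432).

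Genes of the hypoxia response passed camera in the upward direction (median 0.53, adjusted p = 0.0289, and adjusted p = 0.430 with an estimated correlation). The 1 of 17 members that passed over all genes, Ankrd37, fell (log2 fold change -2.74, SE 0.29), while adjusted over the list alone Ankrd37 was the 1 lower and 4 were higher, including Higd1a (2.22, SE 0.38), the glucose transporter gene Slc2a1 (1.87, SE 0.46) and Ndrg1 (2.31, SE 0.57). Ankrd37 and Tef overlap genes on the opposite strand. The hypoxia response call ended without control replicate 2 (adjusted p = 0.0612), control replicate 3 (0.0867) or NEC replicate 1 (0.0684). Of 14 circadian clock genes Tef rose (1.42, SE 0.22), and adjusted over the list alone 5 were higher, including Nr1d2 and Cry2, and Per2 was lower (camera adjusted p = 0.0038, and adjusted p = 0.436 with an estimated correlation).

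Neutrophil markers, erythroid markers and antimicrobial and acute phase genes were higher in NEC as lists. Neutrophil markers had a median of 2.66 (camera adjusted p = 0.000206, and adjusted p = 0.430 with an estimated correlation), with 0 of 10 past the test over all genes and 5 higher adjusted over the list alone, such as Il1r2 (log2 fold change 4.10, SE 0.75), Ltf (1.86, SE 0.38) and S100a8 at 0.142 ± 0.127 CPM in control and 5.36 ± 5.53 CPM in NEC. Erythroid markers had a median of 2.42, with 0 of 9 past the test over all genes and 5 higher adjusted over the list alone (camera adjusted p = 0.0127, and adjusted p = 0.436 with an estimated correlation). The globin genes Hbb-bs and Hba-a1 stood at 114 and 57.7 CPM in control and at 617 and 324 CPM in NEC. The call of erythroid markers ended without control replicate 2 (median 1.54, adjusted p = 0.175) or NEC replicate 2 (median 1.02, adjusted p = 0.0723). Without control replicate 3 the median of neutrophil markers was 4.33, and without NEC replicate 3 that of antimicrobial and acute phase genes was 1.09 (adjusted p = 0.0108). Antimicrobial and acute phase genes had a median of 1.85 (camera adjusted p = 0.00182, and adjusted p = 0.620 with an estimated correlation), and of 17 measured Mmp7 rose over all genes and 5 were higher adjusted over the list alone. Lcn2, an iron-withholding protein gene, had 0.372 ± 0.331 CPM in control and 26.6 ± 36.2 CPM in NEC, and Saa3 had 0.248 ± 0.167 and 79.3 ± 130 CPM. Inflammatory cytokines and chemokines did not pass camera (median 0.53, adjusted p = 0.564), and of 17 measured 0 passed over all genes and 2 were higher adjusted over the list alone, Il1b (log2 fold change 3.24, SE 0.84) and Cxcl2, which averaged 0.731 CPM in NEC. The median of inflammatory cytokines and chemokines was 0.21 without NEC replicate 3, 1.21 without control replicate 2, and 1.07 without NEC replicate 1, where the list passed upward (adjusted p = 0.0145). TLR and NF-kB signalling genes had a median of 0.30 with 0 of 19 changed over all genes or adjusted over the list alone (camera adjusted p = 0.250), with log2 fold changes of 1.998 for Lbp and 1.54 for Nfkbia. Leaving out 1 library moved the median between 0.12 and 0.54, Lbp between 1.37 and 2.455 and Nfkbia between 0.76 and 1.81.

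Genes of the suckling enterocyte were lower in NEC as a list (median -1.02, camera adjusted p = 0.000862, and adjusted p = 0.359 with an estimated correlation). Of 14 measured, 0 passed over all genes and 7 were lower adjusted over the list alone. They include Ctsl, at 5320 ± 1487 CPM in control and 1304 ± 331 CPM in NEC, the lactase gene Lct (log2 fold change -1.94, SE 0.39), the neonatal immunoglobulin receptor gene Fcgrt (-2.27, SE 0.48) and Prdm1 (-1.04, SE 0.20), a regulator of the suckling state. The 20 brush border and absorption genes had a median of -0.36 and 1 lower adjusted over the list alone, Lct (camera adjusted p = 0.0794), and the 8 adult-type genes had a median of -0.10 and 1 higher, Mgam (camera adjusted p = 0.784), with 0 changed over all genes in either. The list enterocyte brush border and absorption passed downward without control replicate 2 (adjusted p = 0.0257), NEC replicate 1 (0.0392) or NEC replicate 3 (0.0118), and its median was -0.14 without control replicate 3. Proximal intestine genes were lower (median -1.37, camera adjusted p = 0.0153, and adjusted p = 0.436 with an estimated correlation), with 0 of 5 past the test over all genes and the iron transport genes Cybrd1 (-2.54, SE 0.51) and Slc40a1 (-1.37, SE 0.27) lower adjusted over the list alone. The call of proximal intestine genes ended without control replicate 3 (median -0.41, adjusted p = 0.124) or NEC replicate 2 (0.0688), and their median was -2.15 without control replicate 2. Colon genes, of which 3 were measured, had a median of -1.72 (camera adjusted p = 0.0349, and adjusted p = 0.436 with an estimated correlation), with Aqp8 and Mettl7b lower adjusted over the list alone and 0 changed over all genes. The call of colon genes ended without control replicate 3 (0.114), NEC replicate 2 (0.0918) or NEC replicate 3 (0.109), without a low-count filter (0.123), with the replicate block (0.0651) and with the code prefix as a term (0.0614). Bile acid and ileal genes had a median of -0.041 with Nr0b2 fallen over all genes, the 1 member lower adjusted over the list alone, and 7 others not past the test (camera adjusted p = 0.983).

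**Figure D3:**
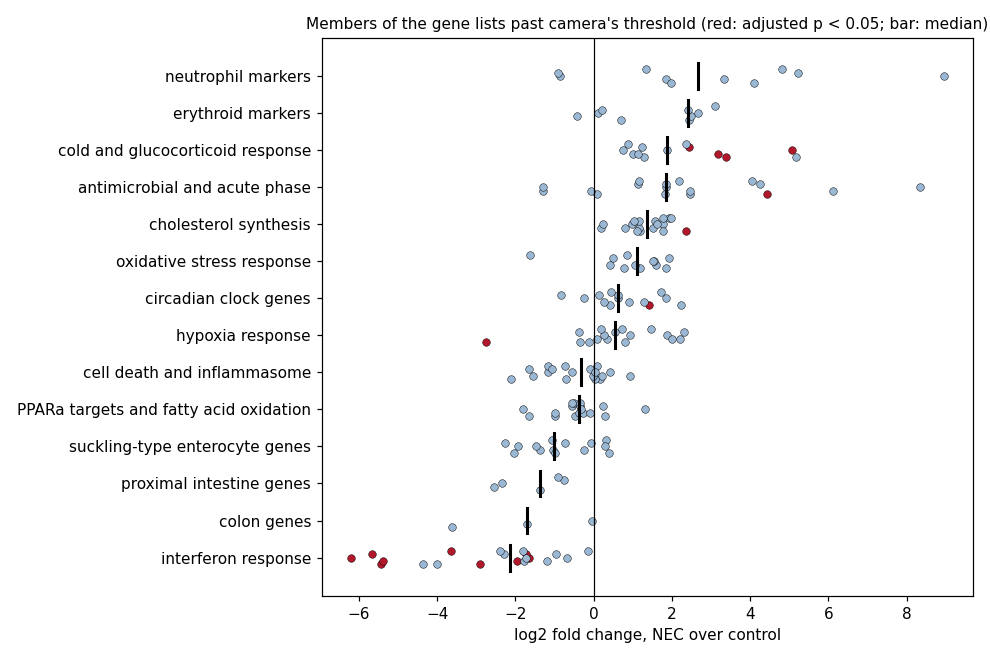
Log2 fold changes (NEC over control) of the members of the 14 lists past camera with the preset correlation, 1 point per gene, red where the gene passed an adjusted p of 0.05 over all genes, with the median as a bar. The median of interferon response genes lies at -2.13 and that of cholesterol synthesis genes at 1.35.

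Cell death and inflammasome genes were lower as a list (median -0.32, camera adjusted p = 0.0259, and adjusted p = 0.436 with an estimated correlation), with 0 of 18 past the test over all genes and 5 lower adjusted over the list alone, among them the pyroptosis effector gene Gsdmd (log2 fold change -1.54, SE 0.32) and Casp1 (-1.18, SE 0.26). PPARa targets and fatty acid oxidation genes were lower (median -0.37, camera adjusted p = 0.0287, and adjusted p = 0.491 with an estimated correlation), with 0 of 17 changed over all genes or adjusted over the list alone, and a log2 fold change of -0.99 for the lipid droplet gene Plin2. The call of cell death and inflammasome genes ended without NEC replicate 2 (0.173), and their median was -0.62 without NEC replicate 3. The PPARa call ended without control replicate 3 (0.141) or NEC replicate 2 (0.457).

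The remaining lists did not pass camera, and the adjusted p of the 28 lists not past it ran from 0.0571 to 0.983. Goblet cell markers came nearest (median 0.85), with 0 of 13 changed over all genes and, adjusted over the list alone, Spdef (log2 fold change 1.30) and Spink4 (2.37) higher and Clca1 (-2.25) lower. The goblet cell markers passed upward without control replicate 1 (adjusted p = 0.0389) or NEC replicate 1 (0.0427). Amino acid and peptide transporters had a median of -0.19, and the glutamate transporter gene Slc1a1 rose 8.02-fold. Adipocyte markers had a median of 0.56 over 3 genes with Fabp4 risen (1.63, SE 0.26), endothelial markers a median of 0.056 over 10 genes with the lymphatic gene Lyve1 risen (2.64, SE 0.33), and pancreas acinar markers a median of 0.057 over 6 genes with Cela1 fallen (-3.06, SE 0.37). These 4 genes passed over all genes and were the only members of their lists to pass adjusted over the list alone. ER stress and amino acid response genes had a median of 0.20 with 0 of 16 changed over all genes, and 3 higher, including Asns (1.36) and Chac1 (2.41), and 3 lower, including Sesn2 (-1.20), adjusted over the list alone. In enteroendocrine and tuft markers (median 0.39, 0 of 17 changed) Gcg was higher adjusted over the list alone (2.30, SE 0.40), and in stem cell and Wnt target genes (median -0.33, 0 of 15 changed) Axin2 was lower adjusted over the list alone (-1.35, SE 0.29). Medians of arginine breakdown (-0.11), cell cycle and smooth muscle genes turned positive with library-size scaling (0.054, 0.077 and 0.095). No member passed in either way in cell cycle (18 genes, median -0.035), tight junctions and adhesion (15, 0.19), smooth muscle (10, -0.043), fibroblast and matrix (12, 0.69), enteric neuron and glia (12, 0.059) or liver (8, -0.36) genes, nor in the T cell and B cell markers. The direction of the camera statistic, the median and the mean differ in sign in T cell, adult-type enterocyte, transporter, arginine breakdown, pancreas acinar, enteric neuron, cell cycle and smooth muscle lists.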

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

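The alternatives of counts divided by 4, the Y-linked covariate and the fit without control replicates 1 and 2 were chosen after seeing the data. The count of 135 (50 higher, 85 lower) rests on few libraries. Leaving out each library in turn gave 0 to 106 genes, 0 to 57 higher, 0 to 80 lower, 0 to 8 interferon members lower, 9 to 17 lists, 0 histone deacetylase and arginine-proline members, and an Hdac8 log2 fold change of -0.61 to -0.31. The fewest calls came without control replicate 1. Fewer samples widen the error of each gene. All of these fits lacked 1 library, so the number of samples alone does not account for a range of 0 to 106 genes. What sets the libraries apart was not tested.

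Counts stayed within 1.5 times of the reported ones under RLE (141), upper quartile (116) and library-size (111) scaling, limma-voom (151), robust=FALSE (151), the stricter filter (186), counts divided by 4 (188) and removal of the 20 most abundant genes (139). No low-count filter gave 247 genes (99 higher, 148 lower), DESeq2 1446 (692 higher, 754 lower, 15 interferon members and 11 histone deacetylase and arginine-proline members) and the code prefix as a term 243 (88 higher, 155 lower). The 4 AG181017 samples gave 25 (7 higher, 18 lower, 4 interferon members), the Y-linked covariate 49 (15 higher, 34 lower, 3 interferon members), the fit without control replicates 1 and 2 gave 1 (0 higher, 1 lower, 0 interferon members), and a threshold of 0.01 gave 0 (0 higher, 0 lower). Of the 1446 DESeq2 calls 135 were the reported genes, of the 243 calls 132, of the 25 calls 14 and of the 49 calls 34. All 14 list calls were lost with an estimated correlation (0 lists) and fry called 2. Camera was not run anew for DESeq2 and robust=FALSE, which leave its input as it was.

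The values do not show that replicate numbers pair the samples, though so few libraries cannot exclude it. Deviations from the group means correlated at -0.141, 0.269 and -0.007 for numbers 1 to 3. The highest of all pairs was 0.358, for control replicate 3 and NEC replicate 1, which share the AG181028 code. Pairs that share AG181017 ran from -0.012 to 0.269. With the replicate block 54 genes were called, 16 higher and 38 lower, 47 of them among the 135.

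Hdac8 kept its sign throughout, which its groups, without overlap, all but fixed in advance where libraries were left out. Its adjusted p stayed outside the threshold throughout, and lay between 0.356 and 0.79 in the fits with more than 1 control. Signs turned only in genes and lists outside the threshold in the tests reported. Hdac7 was -0.26 with the Y-linked covariate and -0.98 without control replicates 1 and 2, where Gm28661 was 0.18 and Gm28437 0.19. With 1 library left out, Hdac2 ran from -0.066 to 0.45, Hdac4 from -0.52 to 0.17, Hdac7 from -0.50 to 1.15, Hdac11 from -0.46 to 0.18, Apoa4 from -0.60 to 0.087 and Apoa1 from -0.23 to 0.28. List medians turned as follows, and the cause was not tested. With library-size scaling they were 0.054 (arginine breakdown), 0.041 (T cell), 0.077 (cell cycle), 0.095 (smooth muscle). With the stricter filter they were 0.51 (T cell), -0.052 (enteroendocrine), -1.58 (pancreas). With limma-voom they were -0.32 (enteroendocrine), 0.38 (ileal), -0.34 (pancreas). With the replicate block they were -0.28 (enteroendocrine), 0.39 (ileal), -0.25 (pancreas). With the code prefix as a term they were -0.22 (enteroendocrine), 0.022 (stem cell), 0.26 (ileal). In the AG181017 samples they were 0.16 (T cell), 0.16 (stem cell), 0.13 (cell cycle), -0.003 (tight junction), -0.008 (enteric neuron), -0.094 (pancreas). With counts divided by 4 they were 0.51 (T cell), -0.034 (enteroendocrine), -1.59 (pancreas). With the Y-linked covariate they were 0.014 (proline), 0.50 (ileal), -0.18 (endothelial), 0.70 (liver). Without control replicates 1 and 2 they were 0.32 (proline), 0.023 (T cell), 0.047 (cell cycle), -0.15 (tight junction), 0.42 (ileal), 0.99 (smooth muscle), -0.62 (endothelial), 0.17 (liver). With each library left out the medians ranged as arginine breakdown -0.30 to 0.013, polyamine -0.082 to 0.25, transporter -0.40 to 0.04, T cell -0.34 to 0.14, B cell -1.20 to 0.70, adult-type -0.27 to 0.074, stem cell -0.52 to 0.039, cell cycle -0.49 to 0.20, tight junction -0.20 to 0.35, ileal -0.20 to 0.29, smooth muscle -0.39 to 0.27, fibroblast -0.59 to 0.94, endothelial -0.44 to 0.28, enteric neuron -0.43 to 0.37, pancreas -0.31 to 0.82, liver -0.52 to 0.078.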

Other observations

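The 6 further gene lists, the leukocyte and enterocyte tests, the test of a more distal segment, the Y-linked covariate, the fit without control replicates 1 and 2, and the genes named from the further lists were chosen after the data were seen. Of 18 genes of MHC class I antigen presentation measured, 4 fell over all genes tested and 11 were lower adjusted over the list alone, with a median log2 fold change of -1.06. The further lists were drawn up with called genes in view, so their counts and camera values are descriptions and no independent evidence of a direction (camera adjusted p = 1.36e-08 over 48 lists for MHC class I, and adjusted p = 0.416 with an estimated correlation). The light chain gene B2m fell from 2114 ± 253 to 661 ± 127 CPM (SD, n = 3 each), and the immunoproteasome genes Psmb8 and Psmb9 and the peptide editor gene Tapbpl fell by 2.41, 2.68 and 1.67 on the log2 scale. Psmb8 and Psmb9 overlap genes on the opposite strand. The heavy chain genes H2-K1 and H2-D1 did not pass, with log2 fold changes of -0.47 and -0.25. Of the other heavy chain genes, H2-T23 was at -1.77 (SE 0.36) and did not pass over all genes (edgeR adjusted p = 0.0811). H2-Q4, H2-Q7 and H2-M3 were at -0.52, -0.67 and 0.03 and did not pass either. Of 7 MHC class II genes 0 passed edgeR over all genes or adjusted over the list alone (median -0.20, camera adjusted p = 0.763).

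Among EGF receptor ligands, which signal epithelial growth, 1 of 6 rose over all genes (Ereg) and 3 were higher adjusted over the list alone, with a median of 1.12 (camera adjusted p = 0.0197, and adjusted p = 0.416 with an estimated correlation). Of 9 laminin genes Lamb3 rose from 1.18 ± 0.160 to 9.11 ± 1.43 CPM and Lama3 fell from 176 ± 42.4 to 34.0 ± 8.75 CPM, and 2 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.451). Lrat, which stores retinol as its ester, fell from 165 ± 13.8 to 13.9 ± 11.1 CPM among 11 retinoid genes with a median of 0.010, of which 1 was higher and 3 lower adjusted over the list alone (camera adjusted p = 0.705). Of 13 glutathione S-transferase genes 1 rose over all genes (Gsta1) and 3 were higher and 1 lower adjusted over the list alone (median 0.91, camera adjusted p = 0.0590).

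The 6 samples allow 10 splits into groups of 3, too few for a share under 0.05. The real split gave 135 changed genes and the highest of the others 2. For lists the values were 14 and 9, for interferon response members lower 9 and 0, and for histone deacetylase and arginine-proline members 0 and 0. The real split was the 1 with the largest value in the first 3, and all 10 were equal in the last. The lowest list count of the other splits was 3, so camera with the preset correlation called lists in all of them.

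Interferon response genes had a median log2 fold change of -2.13 in NEC (25th to 75th percentile -4.10 to -1.71, and a 75th percentile of -1.49 with the covariate). Fewer leukocytes would lower their markers alike. The 25th percentile of 32 macrophage, T cell and B cell markers was -0.72, which argues against fewer of these cells as the whole cause. Neutrophil markers, not among the 32, were higher as a list (median 2.66). With the Y-linked signal as a covariate the median was -2.08 with 16 of 20 intervals below 0, so that signal did not account for the whole fall. The count of members lower went from 9 to 3, for a reason that was not tested. Without control replicates 1 and 2, which left 1 control, the median was -2.19. The Y-linked signal stands in for sex imperfectly. It ran from 0.618 to 1, relative to the highest library, among NEC libraries that all had Xist near 0. Only 1 control had Xist near 0, so sex as a cause is not settled. With the code prefix as a term the median was -1.91. Within the AG181017 and AG181028 samples the median of plain differences of mean log2 CPM, another measure, was -2.16 and -1.70. Each prefix held as many control as NEC samples, so a shift of a whole prefix would fall on both groups alike. By design such a shift cannot separate the groups, and these values are no test of it. Feeding, hypoxia and cold came together in NEC and stay open, as does a difference in exposure to microbes or virus, which was not tested, so a lower interferon response in the stressed intestine may be biological only as a hypothesis.

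Suckling-type enterocyte genes had a median log2 fold change of -1.02 in NEC. Fewer enterocytes would lower other enterocyte genes alike. For 19 such genes outside the list the median was -0.36 and the 25th percentile -0.69, above the suckling median, with a 75th percentile of -0.09. The suckling list ran from a 25th percentile of -1.445 to a 75th of -0.12. These ranges overlap, so the values do not settle whether fewer enterocytes were the whole cause. The list enterocyte brush border and absorption passed downward in 3 of 6 fits that left out 1 library, with a median as low as -0.58. A more distal segment in the NEC samples cannot be told apart from a change within the tissue. Proximal genes had a 75th percentile of -0.91, while ileal genes ran from a 25th percentile of -0.57 to a 75th of 0.78, and the segment is not given in the sources used here. Members of the bile acid and ileal list went both ways, 4 positive and 4 negative, and favour neither reading. The ileal bile acid transporter gene Slc10a2 was higher but not called (log2 fold change 4.93, SE 1.57, edgeR adjusted p = 0.198). Its edgeR log2 fold change ran from 3.94 to 10.6 with 1 library left out. As a plain difference of mean log2 CPM, another measure, it was 3.62 within the AG181017 samples and 7.56 within the AG181028 samples. Nr0b2, the called member, fell (-6.66, SE 0.55). The 3 colon genes measured had a median of -1.72, with Aqp8 at -3.62 and Mettl7b at -1.72. A more distal segment short of the colon need not raise them, so they do not decide the question.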
